A study of Mus musculus with 10 samples.

How the data were processed

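N6-methyladenosine (m6A) is a methyl mark on adenosines of messenger RNA, and Mettl14 is a subunit of the enzyme complex that writes it. Per the labels, neural progenitor cells were isolated from the hypothalamus of mouse embryos with a floxed Mettl14 gene and cultured with FGF2 and EGF. Lentivirus carrying EGFP with Cre recombinase, which deletes the floxed part of the gene, gave knockout cells, and EGFP alone gave control cells. EGFP-positive cells were sorted, polyadenylated RNA was fragmented, and fragments with m6A were enriched with an antibody. The labels list 4 control and 4 knockout m6A immunoprecipitation (IP) libraries, with 1 input library of each genotype.

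The submitters' processing notes name bcl2fastq 2.17.1.14, Trimmomatic 0.32 and STAR 2.5.2a, without saying what each step was. They also name the mouse build GRCm38.p6 and the human build GRCh38.p13. The peak caller, the counting tool and the set of libraries used for peak calling are not given in the sources used here. The files analysed were 1 list of 21195 peaks and a table of the same 21195 peaks, whose intervals, strands and scores were the same in both. The deposited counts are whole numbers of reads per peak, with 1 column for input and 1 for IP, per the file headers. These columns name no library and no genotype, and whether they are sums or rounded means over libraries is not given in the sources used here. The deposited log2 fold change was taken to compare IP with input for each peak. Its header names no groups, and the normalization behind it is not given in the sources used here. The deposited p-values and adjusted p-values were taken to belong to the same comparison, and the test that gave them is not given in the sources used here. The deposited score equalled minus log2 of the adjusted p-value in all 21195 rows, within a tolerance of 1e-06. The fold changes, p-values and scores are all the authors' own values.

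The deposited log2 fold change was not a plain ratio of the deposited counts. It exceeded the log2 ratio of the reads (pseudocount 0.5) by a median of 1.88 (SD 0.527 across peaks), so 2389 peaks (11.3%) had fewer IP than input reads and still a positive log2 fold change. Spearman's correlation between both measures was 0.854 across peaks, which are not independent replicates. If the adjustment was that of Benjamini and Hochberg, the peak with the largest p-value implied 21214 tests, 19 more than the peaks listed. The other rows were not checked against this adjustment. All 21195 peaks were written as a single block, so a peak that crosses introns spans them. The median peak spanned 891 bases, and 2757 peaks spanned over 10000 bases.

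The comparison of knockout with control set out before the data were examined could not be made, because no column belonged to a genotype or a library. There was also no replicate from which an SD could be taken. Peaks were therefore described as a single pooled set. Intervals given beside a ratio of IP to input reads are exact Clopper-Pearson 95% intervals. They take the deposited numbers as counts and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Where a peak had 0 input reads, the ratio was computed against a floor of 3 reads and is written as a lower bound.

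No genome sequence or exon annotation was used here. Results planned on transcript region, stop codons, the DRACH sequence motif and exon length were not run. The gene table used was RefSeq for GRCm38.p6, the mouse build of the processing notes, with gene spans but no exons or strands. Of the peaks, 98.1% overlapped a RefSeq gene span, against 59.7% after a shift of 1000000 bases. The deposited gene identifiers were not in this table, so each peak was named by position. A gene ID entry (the 1 or more identifiers of a peak) took the name of a gene if its peaks overlapping a single RefSeq gene all pointed to that gene. Entries without such a peak took the single protein-coding gene, or single unclaimed gene, shared by all their peaks. An overlap counted only if it covered 50% of the shorter of peak and gene. Where entries on both strands pointed to a gene, the strand with at least 10 times the IP reads of the other kept the name. Otherwise the gene stayed unnamed, as 327 genes did. In all, 9130 of 11184 entries and 17691 peaks were named, and 3504 peaks were left unnamed.

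This naming rule was not set before the data were examined. It is the last of several: 3 earlier rules were replaced after wrongly named genes had been seen, and the list results under 2 of those had already been seen when the last rule was set. The earliest used only peaks with a single identifier, the next accepted any overlap, and the one after required the gene to cover 50% of the peak. Of the peaks named by the last rule, 47, 39 and 5 had carried another gene's name under these rules, in that order. All list, strength and position results were recomputed under each of the 3.

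The groups of samples, the planned tests, the gene lists and the rule for named genes were fixed before the data were examined. The text names up to 4 genes of each list with the strongest peak by the authors' log2 fold change, the 10 genes with the strongest peak, the 5 genes with the most peaks, and all genes of the m6A list. The 19 gene lists were tested with Fisher's exact test (two-sided), which compared the share of list members with at least 1 named peak with that of all other RefSeq protein-coding genes. P-values were adjusted over the 19 lists by the Benjamini-Hochberg method. Which genes were expressed was unknown, so this background also holds silent genes. An alternative drew genes matched on genomic span in 20 bins 10000 times, in place of the planned match on spliced length. This permutation test within span bins took as many other genes from each bin as the list had there, without replacement. Peak strength was the deposited log2 fold change of a gene's strongest peak. The median of a list was tested against other protein-coding genes with a peak by a two-sided permutation test with 100000 resamples. Peak midpoints were sorted into 10 equal bins along the gene span, with the deposited strand giving the direction, and compared with 1000 random placements of each peak within its gene. This measure of position took the place of the planned transcript regions after the data had been seen.

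On simulated lists of 40 genes drawn from 21900 genes, Fisher's test called 3.5% of 200 unchanged lists and 93.5% of 200 lists whose odds of a peak were raised to 4. The span-matched test called 4.5% and 98.5% of them. On 8481 genes with a peak, the strength test called 4% of unchanged lists and 85% of lists shifted by 0.6 on the log2 scale. For unchanged lists of genes with long spans, Fisher's test called 79.5% and the span-matched test 4.5%. These long-span lists were made to differ from other genes in span alone, the trait on which the second test matches. No simulated list was made to differ in expression. The rates therefore do not show how often either test would call a list that differs from other genes in expression alone. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.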

Results

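The m6A map of cultured mouse hypothalamic neural progenitor cells held 21195 peaks, intervals in which RNA fragments were enriched by the m6A antibody over input RNA. The 17691 peaks that could be named lay in 8481 of 21900 RefSeq protein-coding genes (38.7%) and in 470 long noncoding RNA genes. Counting any overlapping peak, named or not, 9898 protein-coding genes were overlapped. Of the 9092 genes with a named peak, 4410 had a single peak, 417 had 5 or more, and the median was 2. The series was laid out to compare control cells with Mettl14 knockout cells (4 m6A IP libraries and 1 input library each). The peak table carried no column for a genotype or library, so m6A in the knockout was not compared with the control here. Each peak had 1 pooled value for input reads and 1 for IP reads, with no replicate values and so no SD. Over all peaks these came to 26.6 M input and 72.3 M IP reads (M, 1000000), with a median of 466 input and 864 IP reads per peak, and the depth of single libraries was unknown. In the authors' deposited table the median log2 fold change of IP over input was 3.06 (8.34-fold), with 1.63 and 4.74 as the 5 and 95 percentiles. It was above 1 for 99.2% of the peaks in the authors' deposited table, and 8 peaks had an adjusted p of 0.05 or more.

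The targeted gene, Mettl14, held m6A peaks, as did most genes of the m6A machinery. Mettl14 (chromosome 3, minus strand) had 2 peaks. The stronger, at 123371222 to 123371496 on GRCm38.p6, had 367 input and 1265 IP reads, a ratio of 3.45 (95% interval 3.07 to 3.88) and a log2 fold change of 4.41 in the authors' deposited table. The other, at 123369647 to 123369771, had 886 input and 688 IP reads and a log2 fold change of 1.49 in the authors' deposited table. Whether either peak lay in the deleted part of the gene was not analysed here. Of 26 genes of the m6A list, 17 had a named peak (65.4%, against 38.7% of other protein-coding genes; Fisher's exact test, adjusted p = 0.0135). Against genes of like genomic span, of which 47.5% had a peak, the difference was not past the threshold (permutation test within span bins, adjusted p = 0.108). Under 2 of 3 earlier rules for naming peaks, by single identifiers and by any overlap, it was (22.4 and 24.5 percentage points; permutation tests, adjusted p = 0.0471 and 0.0277).

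Among the m6A readers, proteins that bind the mark, the strongest peaks lay in Ythdf3, Ythdc1 and Ythdf2. The Ythdf3 peak on chromosome 3 (16189541 to 16214474) had 6307 input and 29084 IP reads, a ratio of 4.61 (95% interval 4.49 to 4.74) and a log2 fold change of 5.09 in the authors' deposited table. For Ythdc1, which had 6 peaks, and Ythdf2 the authors' deposited table gave 4.87 and 4.76, and for Ythdf1 3.76. The writer complex was represented by Wtap, Zc3h13, Rbm15 and Virma, whose strongest peaks had log2 fold changes of 4.73, 4.31, 4.18 and 4.12 in the authors' deposited table. Zcchc4 and Mettl16, methyltransferases outside that complex, had 4.09 and 3.08 in the authors' deposited table. Of the demethylases, Fto had its strongest peak at 4.61 and Alkbh5 at 2.15 in the authors' deposited table, and the Alkbh5 peak held fewer IP than input reads (323 and 363). Values for Hnrnpa2b1, Prrc2a, Igf2bp2 and Fmr1 were 4.24, 3.82, 3.29 and 2.56 in the authors' deposited table, and the Fmr1 peak too held fewer IP than input reads (1161 and 1511, a ratio of 0.768 with a 95% interval of 0.711 to 0.830). Such ratios are not corrected for depth, so a ratio under 1 does not show depletion. The 9 genes without a named peak were Mettl3, Mettl5, Cbll1, Hnrnpc, Igf2bp1, Igf2bp3, Pcif1, Rbm15b and Ythdc2. A peak that could not be assigned to a gene overlapped 5 of these, Cbll1, Igf2bp3, Mettl5, Pcif1 and Rbm15b.

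The highest fold changes belonged to peaks with few or no input reads. In the authors' deposited table the 4 highest log2 fold changes were 9.37 for Coa5, 8.86 for Kbtbd6, 8.60 for Zic2 and 8.59 for Cep128. These peaks had 0 input reads and 49, 40, 41 and 44 IP reads. Without correction for depth, this is at least 16.3-fold, 13.3-fold, 13.7-fold and 14.7-fold higher against a floor of 3 reads per peak. This floor leaves out the counting error of the IP reads, and the exact 95% lower limits that include it were 12.8, 10.4, 10.6 and 11.4. Zic2 encodes a zinc finger transcription factor of the developing forebrain, and its other 3 peaks had log2 fold changes of at most 2.68 in the authors' deposited table. The next were Kcnh5, Samd12, Tslp, Gm8666, Clpb and 2810403D21Rik, with log2 fold changes between 7.40 and 6.42 in the authors' deposited table and 1 to 14 input reads. The peak of 2810403D21Rik had 14 input and 210 IP reads, a ratio of 15.0 with a 95% interval of 8.74 to 27.9. The most peaks lay in Zfp469, with 18, followed by Dst and Zfhx4 with 13 each, and Ank2 and Kmt2a with 12 each. Ank2, which encodes the membrane scaffold ankyrin B, had 14887 input and 85144 IP reads in its strongest peak, a ratio of 5.72 (95% interval 5.62 to 5.82). Kmt2a encodes a histone H3 lysine methyltransferase, and its strongest peak had 544 input and 2011 IP reads.

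Lists of genes that act on chromatin, on mRNA and in growth and Wnt signalling held m6A peaks more often than other genes. A named peak was found in 39 of 46 genes of mRNA decay and translation control (84.8%) and 50 of 62 histone and DNA modifiers (80.6%). In the C2H2 zinc finger list 365 of 467 genes had a named peak (78.2%). This list was set by symbol and may hold zinc finger genes of other types. Of other protein-coding genes, 38.6%, 38.6% and 37.9% had a peak (Fisher's exact test, adjusted p = 7.58e-10, 1.21e-10 and 1.58e-67). Insulin, leptin and growth signalling followed with 29 of 40 genes (72.5%), Wnt with 26 of 37 (70.3%) and FGF and EGF signalling with 24 of 35 (68.6%; Fisher's exact test, adjusted p = 9.02e-05, 0.000403 and 0.000952). Cell cycle regulators had a peak in 34 of 52 genes (65.4%) and neural progenitor markers in 15 of 24 (62.5%; Fisher's exact test, adjusted p = 0.000403 and 0.0302). For these 8 lists the share was also higher than in genes of like genomic span (permutation test within span bins), with adjusted p between 0.000475 and 0.0477. The former comes from p = 1e-04, the smallest that 10000 draws of this permutation test can give. For FGF and EGF genes that difference was not past the threshold under 2 of 3 earlier naming rules (permutation tests, adjusted p = 0.214 and 0.229). Hedgehog with 12 of 18 genes (66.7%) and Notch with 19 of 30 (63.3%) were past the threshold in Fisher's exact test (adjusted p = 0.0355 and 0.0135) and not against genes of like span (adjusted p = 0.202 and 0.0673). With peaks above the median log2 fold change alone, Notch, Hedgehog and cell cycle genes were no longer past the threshold, and progenitor markers stood 4.84 percentage points under other genes (difference -4.84; Fisher's exact test, adjusted p = 0.860). Which genes these cells express was unknown, so the other genes include silent ones.

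**Figure D1:**
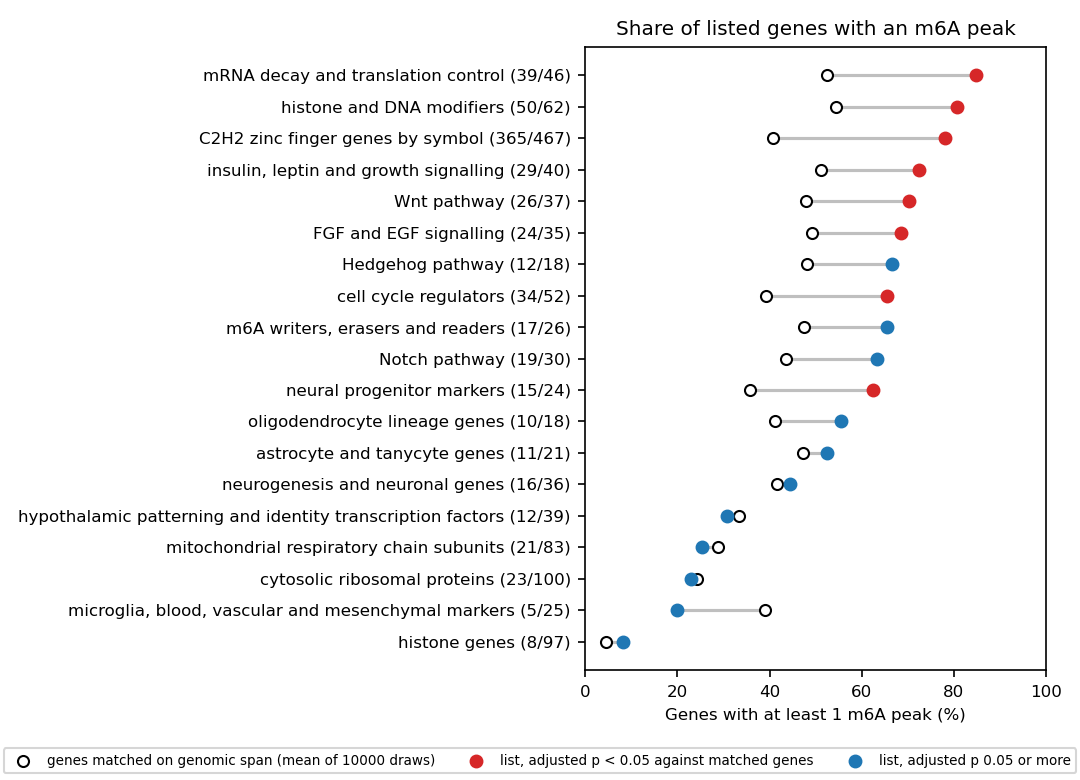
Percent of genes with at least 1 named m6A peak for each of 19 gene lists (filled points, with peak and member counts beside the name) and for protein-coding genes matched on genomic span (open points, mean of 10000 draws). Red points mark the 8 lists with an adjusted p under 0.05 against matched genes, all of them to the right of their matched genes.

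In the growth list the strongest peaks were in Pik3ca, Bdnf, Tsc1 and Pik3r1, with log2 fold changes of 5.81, 5.55, 5.51 and 4.71 in the authors' deposited table. Pik3ca, the catalytic subunit of a phosphoinositide 3-kinase, had 1693 input and 12232 IP reads on chromosome 3 (32436375 to 32436499), a ratio of 7.23 (95% interval 6.87 to 7.61). The Tsc1 peak had 13 input reads. Among FGF and EGF genes, whose ligands were in the culture medium, the authors' deposited table gave 5.31 for the ERK phosphatase Dusp6, 5.13 for the receptor Egfr, 4.95 for Etv1 and 4.80 for Grb2. In the Wnt list the values were 4.83 for Csnk1a1, 4.71 for the co-receptor Lrp6, 4.34 for Tcf7l2 and 4.32 for Wls in the authors' deposited table. The Hedgehog receptor Ptch1 had 4.76, with Gli3, Gpr161 and Disp1 at 4.26, 4.23 and 4.06 in the authors' deposited table. In the Notch list the authors' deposited table gave 5.63 for the protease Adam10, 4.50 for Maml2, 4.31 for Maml3 and 4.14 for the receptor Notch2. Notch2, Nr2e1, Pax6 and Notch1 led the progenitor markers, at 4.14, 3.97, 3.93 and 3.74 in the authors' deposited table. Cell cycle genes were led by the CDK inhibitor Cdkn2d at 5.77, then E2f3, Ccne2 and Mycn at 4.60, 4.33 and 4.13 in the authors' deposited table. Among histone and DNA modifiers the values in the authors' deposited table were 5.29 for Hdac2 (20 input reads), 5.07 for Asxl3 and Arid1b, and 4.83 for Kat6a. The mRNA decay and translation list was led by Upf2, Pum2, Cnot4 and Smg1, at 5.09, 4.92, 4.86 and 4.72 in the authors' deposited table.

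Ribosomal protein, respiratory chain and histone genes held m6A peaks less often than other genes. Against genes of like span none of the 3 lists was past the threshold, and for histone genes the direction turned. A named peak was found in 23 of 100 genes of the ribosomal protein list (23.0%, against 38.8% of others; Fisher's exact test, adjusted p = 0.00200). This list was set by symbol, and Rps6ka5, Rps6kb1 and Rps6ka4 in it encode kinases, at log2 fold changes of 4.97, 4.34 and 4.21 in the authors' deposited table. Rps24, a ribosomal protein gene, had 4.66 in the authors' deposited table. Without the genes that only share the prefix, a choice made after the data were seen, 14 of 81 had a peak (17.3%). For mitochondrial respiratory chain subunits the count was 21 of 83 (25.3%; Fisher's exact test, adjusted p = 0.0200), with Ndufb1, Atp5j, Ndufs1 and Ndufs4 the strongest at 4.92, 4.69, 4.68 and 4.48 in the authors' deposited table. The Ndufb1 peak rested on 6 input and 33 IP reads. Histone genes had a peak in 8 of 97 (8.25%; Fisher's exact test, adjusted p = 1.21e-10), with H2ac19 at 4.77 the strongest and H2ax at 3.69 in the authors' deposited table. The H2ax peak, on chromosome 9 at 44335444 to 44336068, had 10710 input and 61610 IP reads. The libraries were made from polyadenylated RNA, and whether it held transcripts of the histone genes without a peak was not known. The lists had median gene spans of 3.45, 7.08 and 0.496 kb, and of genes of like span 24.3%, 28.9% and 4.55% had a peak (permutation test within span bins, adjusted p = 0.859, 0.665 and 0.102). Under earlier naming rules the ribosomal list was lower than genes of like span by single identifiers (-9.39 percentage points), and histone genes were higher by single identifiers (4.74) and by any overlap (9.54; permutation tests, adjusted p = 0.0496, 0.0444 and 0.00038).

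Markers of cell identity outside the progenitor list were not past the threshold. Hypothalamic transcription factors had a named peak in 12 of 39 genes (30.8%; Fisher's exact test, adjusted p = 0.348). Nr2f2, Tbx3, Six3 and Irx5 were the strongest, at log2 fold changes of 4.98, 4.23, 3.54 and 3.52 in the authors' deposited table. The Tbx3 peak, on chromosome 5 at 119671819 to 119672018, had 23705 input and 155979 IP reads, a ratio of 6.58 (95% interval 6.49 to 6.67). Neuronal genes had a peak in 16 of 36 (44.4%; Fisher's exact test, adjusted p = 0.497), with Sox4 and Neurod1 at 5.04 and 4.70 in the authors' deposited table. The Sox4 peak rested on 4 input reads. Astrocyte and tanycyte genes stood at 11 of 21 (52.4%; Fisher's exact test, adjusted p = 0.293), with Dio2, Aqp4, Cd44 and Tnc at 4.37, 4.19, 4.14 and 3.88 in the authors' deposited table. Oligodendrocyte lineage genes stood at 10 of 18 (55.6%; Fisher's exact test, adjusted p = 0.182), with Zfp488, Sox6 and Pdgfra at 4.03, 4.02 and 3.75 in the authors' deposited table. Microglial, blood, vascular and mesenchymal markers had a peak in 5 of 25 genes (20.0%; Fisher's exact test, adjusted p = 0.0812), and 2 of these 5, Pdgfra and Cspg4, also belong to the oligodendrocyte list.

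Zinc finger genes held stronger peaks than other genes, and ribosomal protein genes weaker ones. The median log2 fold change of the strongest peak in the authors' deposited table was 3.98 in 365 genes of the C2H2 zinc finger list, set by symbol, and 3.49 in other genes with a peak (difference 0.49; permutation test, adjusted p = 0.00019 from p = 1e-05, the smallest that 100000 resamples can give). Of the 365 genes, 252 lay above the median of the others. Zfp992, Zfp52, Zfp974 and Zfp937 were the strongest, at 6.24, 6.15, 6.14 and 6.05 in the authors' deposited table, on 21, 52, 7 and 102 input reads. C2H2 zinc finger genes have similar sequences, and how reads that match several of them were counted is not given in the sources used here. In the 23 genes of the ribosomal protein list the median in the authors' deposited table was 2.59, against 3.51 in other genes (permutation test, adjusted p = 0.00627), and 8 of the 23 lay above the median of the others. With the mean over a gene's peaks in place of the strongest the ribosomal difference was -0.49, and under an earlier naming of peaks by single identifiers it was -0.22, neither past the threshold (permutation tests, adjusted p = 0.150 and 0.651). In the narrower ribosomal list, a choice made after the data were seen, 14 genes had a peak. Their median was 2.37, with 3 above the median of the others (permutation test, adjusted p = 0.0038). None of the other 17 lists was past the threshold, with adjusted p from 0.0739 for cell cycle regulators and respiratory chain subunits to 0.943 (permutation tests). The median of the m6A list was 4.18 in the authors' deposited table, with 13 of 17 genes above the median of the others (permutation test, adjusted p = 0.123).

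**Figure D2:**
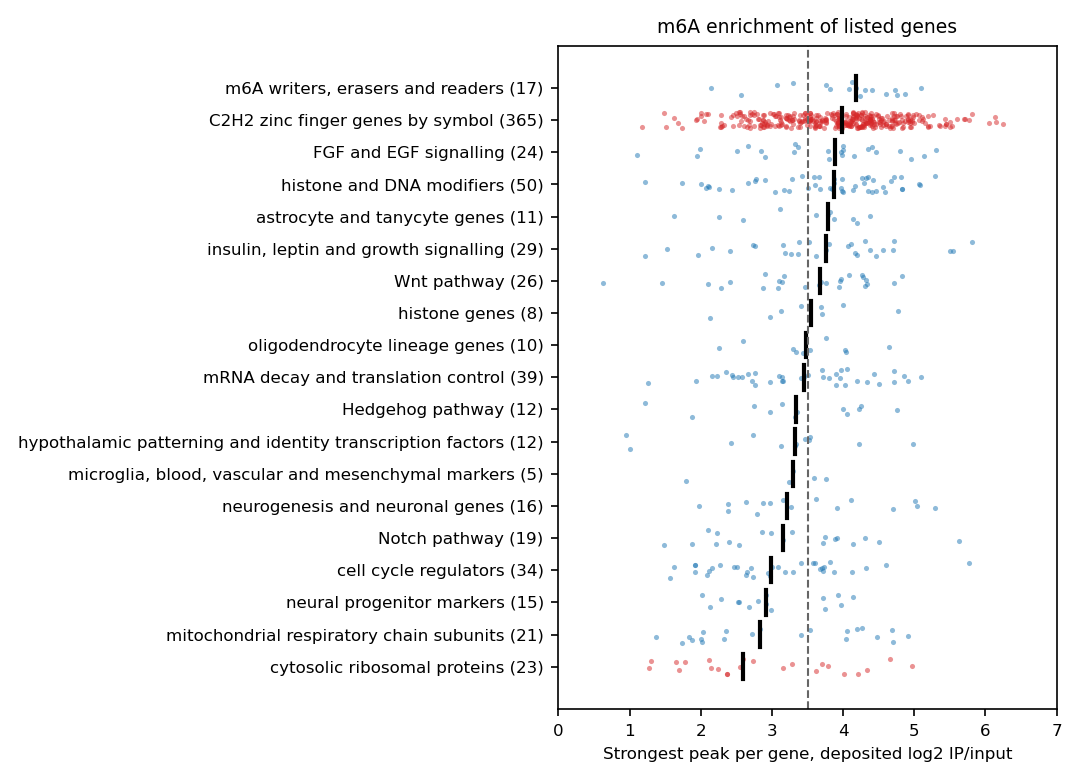
Deposited log2 fold change of IP over input of the strongest peak of each gene with a peak (points, spread vertically at random), by gene list with the number of genes in brackets. Black bars are list medians, the dashed line is the median of all protein-coding genes with a peak (3.51), and red lists, C2H2 zinc finger genes at 3.98 and ribosomal proteins at 2.59, had an adjusted p under 0.05.

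The peaks gathered at the 3' end of genes. Of 15752 peaks that lay inside the span of their protein-coding gene, 39.3% had their midpoint in the 3' bin, the last of 10 equal bins of the span, against 6.80% (SD 0.200 over 1000 placements) when placed at random (permutation test, p = 0.000999, the smallest that 1000 placements can give). The 5' bin held 7.53%, against 6.80% at random (p = 0.000999 by the same permutation test). Among peaks above the median log2 fold change of the authors' deposited table the 5' bin held fewer peaks than at random (5.17% against 6.31%; permutation test, p = 0.000999), and among peaks that overlap 1 gene its excess was not past the threshold (permutation test, p = 0.118). In genes of at most 5000 bases the 3' bin held 13.3%, against 3.13% at random (permutation test, p = 0.000999). Gene spans include introns, so the random placements are not a background of exons. In 510 genes with peaks in both end bins the strongest peak of each bin was compared. The mean difference, 3' minus 5', was 0.56 (SD 1.27 across genes) on the log2 scale of the authors' deposited table. The 3' value was the higher in 333 genes against 177 (sign permutation test, p = 1e-05, the smallest that 100000 resamples can give). Over all genes the 3' bin held 6189 peaks and the 5' bin 1186. A maximum over more peaks tends to be higher, and this was not corrected for. Over all peaks of a bin, the median in the authors' deposited table was 2.99 in the 3' bin, 2.59 in the 5' bin and 2.98 to 3.24 in the bins between.

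**Figure D3:**
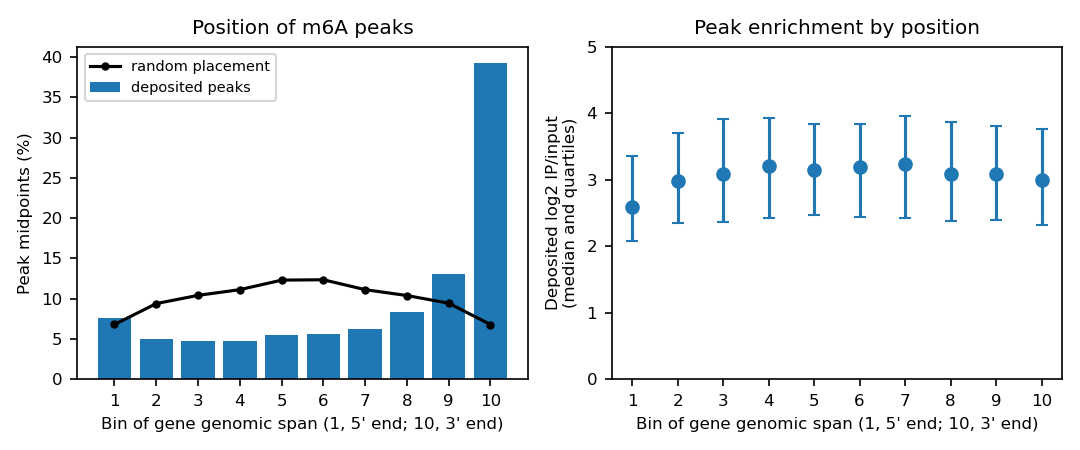
Left, percent of 15752 peak midpoints in each of 10 bins of the genomic span of their gene, from the 5' to the 3' end (bars), and the mean of 200 random placements within the same genes (line). Right, median (points) and quartiles (error bars) of the deposited log2 fold change of the same peaks, where bin 10 at the 3' end holds 39.3% of the peaks and bin 1 has the lowest median, 2.59.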

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

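The alternatives on peak naming, the narrower ribosomal list, the read ratio, the deposited score, input reads and peak position were chosen after seeing the data. Of 356 values under alternatives that changed the data used, 291 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times. The excess of peaks in the 3' bin did so under 7 of 7, and it ranged from 10.2 points in genes of at most 5000 bases to 42.3 for peaks of at most 1000 bases, against 32.5. With peaks above the median log2 fold change (10597 peaks) 7 lists held peaks more often in place of 11. Differences in share, in percentage points, were then -4.84 for progenitor markers, a reversed direction, 7.68 for Notch, 18.8 for Hedgehog and 5.11 for cell cycle genes, none past the threshold (adjusted p 0.158 to 0.860). Against genes matched on genomic span 0 lists held peaks less often in place of 3. The differences were 17.9 for the m6A list, 19.8 for Notch, 18.6 for Hedgehog, -1.28 for ribosomal proteins and -3.55 for respiratory subunits, none past the threshold, and a reversed 3.69 for histone genes (permutation test, adjusted p = 0.102). Against matched genes under the 3 earlier naming rules (single identifiers, any overlap, 50% of the peak) 1 (ribosomal proteins, -9.39, adjusted p = 0.0496, permutation test), 0 and 0 lists were lower. The differences were 19.9, 18.7 and 19.5 for Notch, 24.7, 17.7 and 18.3 for Hedgehog and -2.03, -4.31 and -3.73 for respiratory subunits, none past the threshold. Histone genes were reversed at 4.74, 9.54 and 2.63 (permutation test, adjusted p = 0.0444, 0.00038 and 0.243). FGF and EGF genes were not past the threshold by single identifiers (11.5) and any overlap (12.4), ribosomal proteins by any overlap (-0.0812) and 50% of the peak (-0.463), and the m6A list by 50% of the peak (17.6). By the deposited score 3 lists had stronger peaks in place of 1, with differences in score of 54.8 for the m6A list and 30.2 for histone and DNA modifiers. Cell cycle genes were weaker past the threshold by the mean of the peaks (-0.52) and by the read ratio (-0.64), and 2 lists were weaker by the read ratio. Ribosomal proteins were not past the threshold by the mean of the peaks (-0.49) or by single identifiers (-0.22), where 0 lists were weaker. In the 5' bin the difference from random placement was -1.14 points for peaks above the median, reversed, and 0.343 for peaks overlapping 1 gene (permutation p = 0.118). Other reversed differences were not past the threshold before or after. For the share of neuronal genes they were -0.668 (peaks above the median), -0.753 (any overlapping peak) and -2.62 (single identifiers, matched genes). By the mean of the peaks strength was reversed for astrocyte (-0.0066), vascular (0.16), modifier (-0.0692) and histone genes (-0.0269), and by the read ratio for hypothalamic (0.49), oligodendrocyte (0.11), vascular (0.0608) and Hedgehog genes (0.17). By score it was reversed for oligodendrocyte (7.14), vascular (4.30), mRNA decay (0.630) and histone genes (-6.89), and within deciles of input reads for oligodendrocyte (0.0174), Hedgehog (0.14) and histone genes (-0.29). Under the 3 earlier naming rules it was reversed for histone genes (-0.38, -0.46 and -0.11). For all these shifts the cause was not tested. The removal of duplicate intervals tested nothing, as 0 were found, and is not counted. No paired analysis was possible because the peak table has no column for a replicate. For want of such columns, of exons or of a genome sequence, the alternatives for differential peaks, peak overlap between genotypes, transcript regions, stop codons, the DRACH motif, exon length, spliced length and detected genes were not run. Peaks with few input reads limit single fold changes, and the depth of each library was unknown.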

Other observations

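The tests on pairs of peaks on opposite strands and on the input reads of oligodendrocyte genes, and the lists of posterior and Y-linked genes, were chosen after the results had been seen. Among the 20 nuclear peaks with the most input reads were peaks in Olig1 (68971 input and 231319 IP reads) and Olig2 (43210 and 228230), transcription factors of oligodendrocyte and motor neuron progenitors, and the highest was in Tmsb4x with 146409 input reads. Progenitor markers differed widely, with 10 input and 33 IP reads in the peak of Sox2 and 16998 input reads in that of Sox1. Both peaks overlapped 2 RefSeq genes, and how reads in such places were counted is not given in the sources used here. The reads therefore do not show how strongly either gene was expressed. Of 45 transcription factors of the posterior and midbrain-hindbrain neural tube, En1, En2, Gbx2 and Hoxa7 had a named peak. The En1 peak on chromosome 1 (120607194 to 120607618) had 13534 input and 34311 IP reads, a ratio of 2.54 (95% interval 2.49 to 2.59).

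Over the protocadherin clusters of chromosome 18 lay 16 peaks in the alpha, 39 in the beta and 50 in the gamma cluster, with median log2 fold changes of 4.13, 3.96 and 3.52 in the authors' deposited table. Over the Hoxa cluster lay 5 peaks on the plus and 12 on the minus strand. The mitochondrial genome had 7 peaks with 2.62% of the input and 1.01% of the IP reads in peaks. Of 4 Y-linked genes 3 had a named peak (Kdm5d, Uty and Ddx3y), and 0 peaks overlapped the long noncoding RNA gene Xist. The nuclear long noncoding RNA genes Malat1 and Neat1 were overlapped by 3 and 4 peaks.

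Ribosomal protein genes held peaks less often than other genes, and histone and DNA modifiers more often. Gene span may account for the former but stays open: the ribosomal list differed from genes of like span by -1.28 percentage points (permutation test within span bins, adjusted p = 0.859), but by -9.39 points under the naming by single identifiers (adjusted p = 0.0496). In the narrower ribosomal list, the difference from genes of like span was -4.20 points (permutation test within span bins, adjusted p = 0.518). The same match left the modifiers 26.1 points higher (permutation test, adjusted p = 0.000475), which argues against span as the whole cause there. Reads shared with pseudogenes stay open for the 81 genes of the narrower ribosomal list. Of these, 11 of 61 with a named pseudogene had a peak (18.0%), against 3 of 20 without (Fisher's exact test, p = 1). No biological explanation was tested, since no column belonged to a genotype, and expression of the genes also stays open.

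Peaks on opposite strands overlapped by at least 90% in 89 pairs. Counting without regard to strand would make the reads of a pair alike, but IP reads differed over 4-fold in 46.1% of the pairs. Counting by strand throughout would leave equality to chance, but 5 pairs, such as that at Pus3 and Hyls1 with 870 input and 2902 IP reads on each strand, were equal within 1% in both columns, against at most 2 in 10000 random pairings. A mixture of both may be present in the table, and no test separated its sources. No biological explanation was tested.

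The high input reads of Olig1 and Olig2 could come from oligodendrocyte lineage cells or from progenitors that express these genes. Input reads were known only inside peaks, so each gene was given its highest input reads per kb among named peaks of at most 3000 bases. If lineage transcripts were abundant as a group, these values would tend to exceed those of the progenitor list. The ratio of the list medians was 0.429 (95% bootstrap interval 0.0352 to 12.5; permutation test, p = 0.585; 9 and 14 genes). Without Olig1 and Olig2, which had prompted the question, it was 0.317 (permutation test, p = 0.255; 7 and 14 genes). The bootstrap interval includes values on both sides of 1, and genes without such a peak could not enter, so the test leaves the source open. Mbp, which encodes a myelin protein of mature oligodendrocytes, had no named peak, which does not show whether it was expressed. Sorting was for EGFP, which selects no lineage, and no biological explanation was tested.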
